A study of Homo sapiens with 21 samples.

How the data were processed

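Cells labelled HepG2 were treated for 24 h with coumarin at 0, 0.001, 0.01, 0.1, 1, 10 or 100 µM in serum-free medium, per the labels, which state 3 biological replicates per group and 21 libraries in all. Per the labels' protocols, RNA was selected on poly(dT) beads before library construction. The table of raw counts per gene was deposited by the authors as whole numbers for each library, and a second deposited table holds FPKM, which the authors scaled by gene length and by 1 total per library. HISAT2, DESeq2 and the GRCh38 build are named in the submitters' processing notes without versions, and the counter, its strand setting and the origin of the total behind FPKM are not given in the sources used here. All 58735 gene identifiers were found in GENCODE release 29, 58690 (99.92%) with the same coordinates. From each library's counts, gene lengths and FPKM the total behind FPKM was computed (genes of at least 20 reads). The part of it beyond the summed gene counts was 1.04% to 8.17%. Below it is called the share of reads outside the counted genes, a reading that was not tested. The smallest share (0.01 µM replicate 3) and the largest (control replicate 3) came with the smallest and largest TMM scaling factors, 0.972 and 1.043. A scaling of the total is therefore not told apart from reads outside genes.

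Samples were grouped by the dose in the labels. Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were filtered by filterByExpr on the groups, libraries were scaled by TMM factors, and the quasi-likelihood F test with robust dispersion was run on all 21 libraries in 1 fit with 14 residual degrees of freedom. Each dose was compared with 0 µM, the mean of the 6 treated groups was compared with 0 µM, and a test of all 7 groups at once was run, over 16699 genes. A slope on log10 dose was fitted to the 18 treated libraries over 16522 genes. P-values were two-sided (except in the test of 7 groups) and adjusted by Benjamini-Hochberg, with a threshold of 0.05, and "rose", "fell" and "changed" are used of what passed it. CPM were computed with TMM-scaled library sizes, and fold changes come from the edgeR fit.

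Lists of genes, 41 in all, and the rule for naming genes were fixed before the data were examined. The 35 lists with at least 5 tested members were tested at 6 doses with camera (limma 3.58.1; log2 CPM with prior count 2, preset correlation 0.01), 210 tests adjusted together, and again with an estimated correlation. For each list the number of members passing is given over all genes tested and adjusted over the list alone. Genes named for a dose are protein-coding, passed the test, had a mean of at least 1 CPM and had all 3 treated libraries on 1 side of all 3 controls: the 12 largest rises and 12 largest falls at 100 µM and 4 each way at other doses. For all treated cells 6 each way were taken with the 18 treated libraries on 1 side of at least 2 controls, and for the trend the 5 steepest slopes each way that passed at 1 CPM or more, coding or not. Of a called list up to 4 members with the smallest p at the dose where the list p was smallest may be named, and of other lists up to 2. CYP2A6, CYP1A1, CYP3A4, VKORC1 and NQO1 are reported whatever their values.

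As chosen in advance, results were also computed with RLE and upper-quartile scaling, no filter, a filter of 1 CPM in 3 libraries, a fit of only the 2 groups compared, the replicate number as a block, leaving out each library in turn, an adjusted p under 0.01, a fold of at least 2, limma on log2 of the deposited FPKM plus 1 or 0.1, DESeq2 1.42.0, prior count 0.5, the dose rank in place of log10 dose, and the trend without 100 µM. Alternatives chosen after seeing the data were control replicate 1 alone (1 control library, with the spread taken from the treated groups, so that a lost call does not show an absent change), the share of reads outside the counted genes as a covariate, removal of each library's trend with transcript GC content and length (known for 99.94% of tested genes), and the 12 libraries at 0.001 to 1 µM as reference. The share of reads outside the counted genes had a mean of 6.70% in control and 2.51% to 4.40% in treated groups. As a covariate it can therefore absorb a treatment effect, and a call lost with it does not show an absent change. It also followed the TMM factors, which are computed from the same counts, so it is not an independent measure of library quality. For genes and counts at 1 dose, only the 6 libraries compared were left out in turn. For overlaps with 100 µM, 20 simulations drew unchanged groups that share the controls.

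Totals of 26984563 to 43375429 counts per library limit precision, and a count of 0 allows up to 3 counts. Floors cover counting error only, since reads amplified by PCR are not independent molecules. The scripts were tested on simulated data with 50 genes changed at each of 4 folds. For 1 dose against control, 68%, 76%, 88% and 100% of genes were recovered at 1.25, 1.5, 2 and 4-fold, with 6 false calls among 16458 genes. For all treated cells these were 74%, 90%, 96% and 100% with 11 false calls, for 7 groups at once 66%, 74%, 86% and 100% with 13, and for the trend 70%, 82%, 96% and 100% with 15 among 16372 genes. Of simulated lists, 3 of 3 shifted lists were recovered, with 0 calls in 203 other tests by camera. Simulated genes varied independently and no library was offset in these tests. They therefore do not give the rate of false calls in the real libraries, where genes of a list can vary together. Genes that share sequence or overlap are reported as uncertain, and genes with too few counts to pass the filter were not tested. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.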

Results

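Messenger RNA levels were measured by sequencing in cells labelled HepG2, a line derived from a human liver tumour, after 24 h in serum-free medium with coumarin, a benzopyrone made by plants. The 7 groups received 0, 0.001, 0.01, 0.1, 1, 10 or 100 µM, with 3 libraries each and 21 in all. Gene counts totalled 26984563 to 43375429 per library. Of 58735 genes, 16699 held enough counts to be tested, and 12613 of these code for protein. Replicates varied by 4.49% (edgeR common biological coefficient of variation). The first principal component of the log2 counts held 16.8% of the variance, and it set the highest dose apart: its mean was 32.25 ± 1.38 (SD, n = 3) at 100 µM, 1.08 at 10 µM and between -7.93 and -5.02 at 0 to 1 µM. The share of reads outside the counted genes, taken from the library total behind the deposited FPKM, was 3.91%, 8.03% and 8.17% in control replicates 1, 2 and 3. Treated groups had means of 2.51% to 4.40%, so control replicates 2 and 3 held the largest shares of the 21 libraries. The TMM scaling factors of control replicates 1, 2 and 3 were 0.9999, 1.04 and 1.043. Those of replicates 2 and 3 were also the largest of the 21 libraries, so the share may be a scaling of the total and not reads.

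Most preset transcripts that mark hepatocytes were near the detection floor in every library, while some keratin and collagen transcripts were abundant and others near the floor. ALB, which encodes serum albumin, TTR, APOC3, RBP4 and FGB, which encode other secreted liver proteins, had 0 counts in all 21 libraries. A count of 0 allows up to 3 counts, or 0.111 CPM (counts scaled to library size) in the smallest library. Of 22 preset hepatocyte secreted-protein genes, 17 had any count, and their sum was 5.12 to 7.26 CPM per library. The most abundant was APOM, which encodes a lipoprotein component, at a mean of 3.33 CPM. HNF4A, the transcription factor that maintains hepatocyte gene expression, had a mean of 0.0193 CPM, and 4 of 15 preset hepatocyte transcription factors reached 1 CPM (NR2F1, NR2F2, FOXA1 and CEBPA). Among preset epithelial and mesenchymal markers, KRT7, a keratin of ductal epithelium, had a mean of 750 CPM (662 to 802) and KRT17 had 143. The intermediate filament gene VIM had 312 and COL3A1, a fibrillar collagen, had 1210. SFN had 170 CPM, COL1A1 114 and PDGFRB 36.1. Other markers of the same lists were near the floor, KRT19 at 0.0573 CPM, KRT20 at 0.0511, KRT14 at 0.124, KRT5 at 0.0022, the epithelial adhesion gene EPCAM at 0.00165, TP63 at 0.0355, COL1A2 at 0.00455 and COL6A3 at 0.0824, and PDGFRA had 0. Endothelial and leukocyte markers stayed below 5 CPM, with ERG at 1.43 and CSF1R at 3.88 as the highest of each. Some further genes were chosen after their values were seen. PRSS56 had 6310 CPM and CPS1, which encodes the first enzyme of the urea cycle, had 4690. KRT8 and KRT18 had 2500 and 1200 CPM, and CDKN2A had 439.

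**Figure D1:**
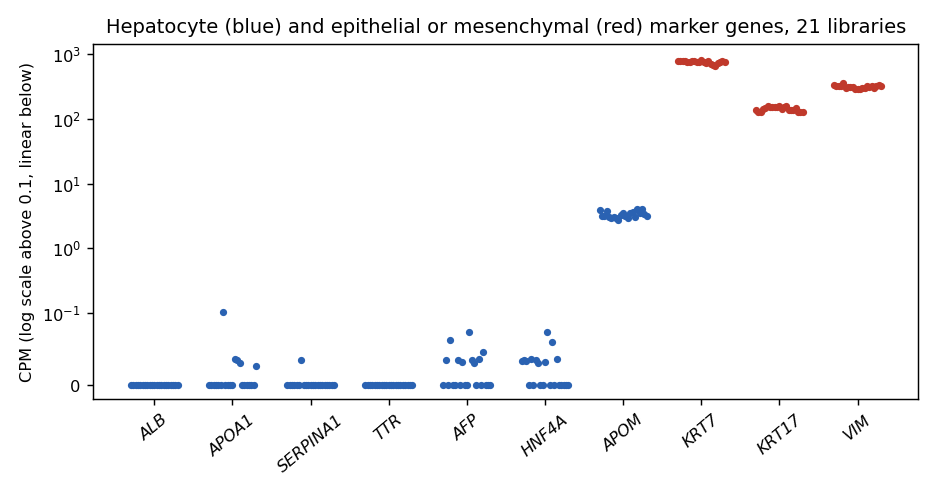
CPM (symmetric log axis) of 7 hepatocyte transcripts (blue) and of KRT7, KRT17 and VIM (red), with 1 point per library for all 21 libraries. ALB and TTR lie at 0 throughout and APOM at 2.78 to 4.08 CPM, whereas KRT7 lies at 662 to 802 CPM.

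The comparison of 100 µM with control asked which transcripts respond to the highest dose, and genes of amino acid synthesis and of the ATF4 stress response rose most. CHAC1, which encodes an enzyme that degrades glutathione (ENSG00000128965, GRCh38 chromosome 15, 40952962 to 40956519), rose 8.02-fold, from 2.40 ± 0.557 to 19.3 ± 0.447 CPM (SD, n = 3; edgeR adjusted p = 9.32e-22). ASNS, asparagine synthetase (ENSG00000070669, chromosome 7, 97852118 to 97872542), rose 6.99-fold, from 1.54 ± 0.138 to 10.8 ± 0.857 CPM (edgeR adjusted p = 2.91e-18). Both genes of the first steps of serine synthesis rose, PSAT1 by 2.99-fold (163.8 ± 3.72 to 490.3 ± 11.1 CPM) and PHGDH by 2.03-fold. The stress-induced pseudokinase TRIB3 rose 2.61-fold, the stress protein gene NUPR1 rose 2.51-fold, and PCK2, mitochondrial phosphoenolpyruvate carboxykinase, rose 2.73-fold. WARS, the cytosolic tryptophanyl-tRNA synthetase, rose 2.53-fold from 147.9 ± 7.56 CPM. Also among the largest rises were the adrenomedullin-family peptide gene ADM2 at 5.32-fold and the activin subunit gene INHBE at 5.14-fold. DDR2, a collagen receptor kinase, rose 4.63-fold, GRB10, an adaptor of the insulin receptor, 2.83-fold, the phosphatase gene PPM1E 2.77-fold and FAM129A 2.76-fold. Of the 24 measured members of the preset ATF4 and amino acid response list, 23 rose, and 23 rose when adjusted over the list alone, with a median log2 change of 1.01. SLC38A2, an amino acid transporter gene, was the exception at a log2 change of 0.07 (edgeR adjusted p = 0.225). The list as a whole rose (limma camera adjusted p = 1.27e-28), also with an estimated correlation (adjusted p = 1.35e-05).

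**Figure D2:**
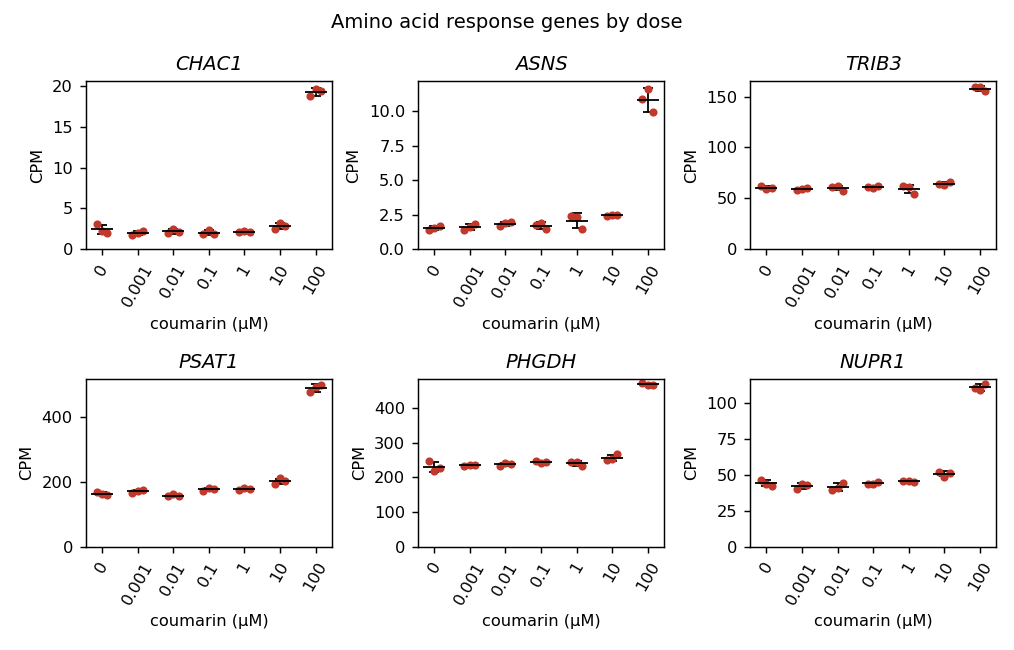
CPM by coumarin dose for CHAC1, ASNS, TRIB3, PSAT1, PHGDH and NUPR1, with a point per library, a dash for the mean and bars for the SD (n = 3 per dose). Means lie near control up to 1 µM and stand apart at 100 µM, where CHAC1 reaches 19.3 ± 0.447 CPM against 2.40 ± 0.557 in control.

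Genes of retinoic acid breakdown, of the aryl hydrocarbon receptor (AHR) response and of inflammation were lower at 100 µM. CYP26A1 and CYP26B1, the hydroxylases that clear retinoic acid, were 4.31-fold and 3.57-fold lower. CYP26B1 (ENSG00000003137, chromosome 2, 72129238 to 72148038) went from 19.2 ± 0.584 to 5.38 ± 0.0575 CPM (SD, n = 3; edgeR adjusted p = 3.98e-19). TGM2, transglutaminase 2, was 3.5-fold lower (16.3 ± 1.30 to 4.67 ± 0.379 CPM). ALDH3A1, an aldehyde dehydrogenase under AHR control (ENSG00000108602, chromosome 17, 19737984 to 19748943), was 3.24-fold lower, from 46.9 ± 4.26 to 14.4 ± 0.624 CPM (edgeR adjusted p = 9.55e-24). The largest fall was that of the transcription cofactor gene LBH, 7.31-fold, at low counts (1.46 ± 0.457 to 0.196 ± 0.0226 CPM). Other named genes that fell were the bradykinin receptor gene BDKRB2 by 4.04-fold, the cytokine TNFSF15 by 3.63-fold, the immune checkpoint receptor VSIR by 3.39-fold and the growth factor binding protein IGFBP1 by 3.29-fold. EHF, an epithelial transcription factor, was 3.87-fold lower, RANBP3L 3.40-fold and the caveolar protein gene CAVIN2 3.13-fold. All 24 genes named here by rule kept their direction and passed the test in every alternative fit run at 100 µM and without any 1 library.

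**Figure D3:**
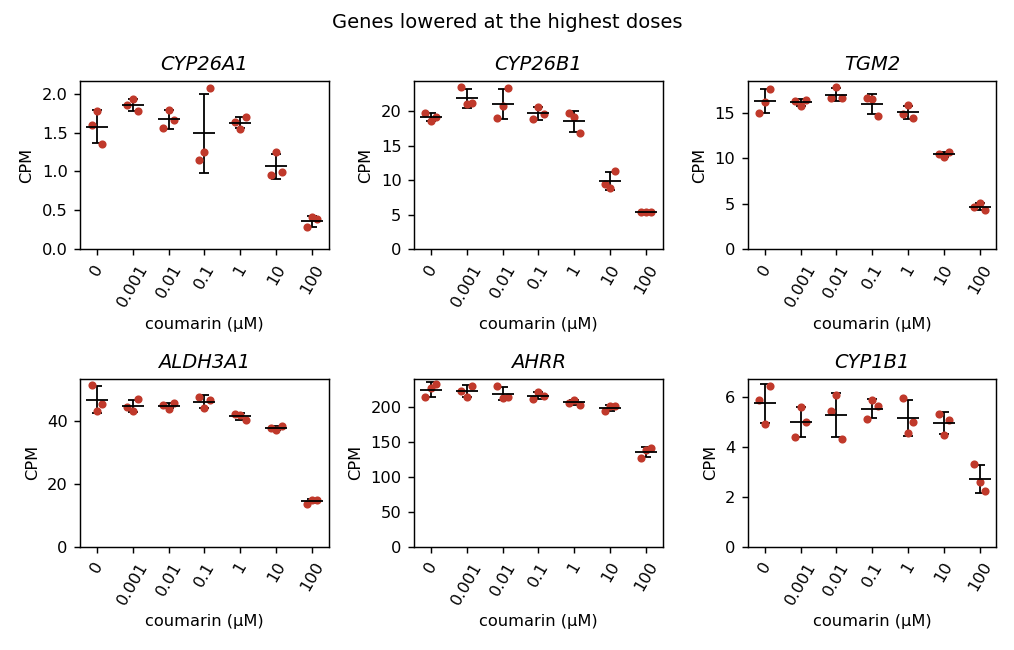
CPM by coumarin dose for CYP26A1, CYP26B1, TGM2, ALDH3A1, AHRR and CYP1B1 (the last chosen after its values were seen), with a point per library, a dash for the mean and bars for the SD (n = 3 per dose). CYP26B1 is lower at 10 µM (9.87 ± 1.31 CPM) and at 100 µM (5.38 ± 0.0575) than in control (19.2 ± 0.584).

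In total, 4558 genes changed at 100 µM (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05), 2409 up and 2149 down, with a median absolute log2 change of 0.27. Changes of at least 2-fold were held by 311 genes, 96 up and 215 down. With upper-quartile scaling 41.4% of the called genes were higher, against 52.9% with the main scaling. Against control replicate 1 alone, the control with the smallest share of reads outside genes, 2222 genes changed (1047 up, 1175 down) in a test whose spread comes from the treated groups, and 2800 changed with that share as a covariate. At an adjusted p under 0.01 the count was 2966.

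**Figure D4:**
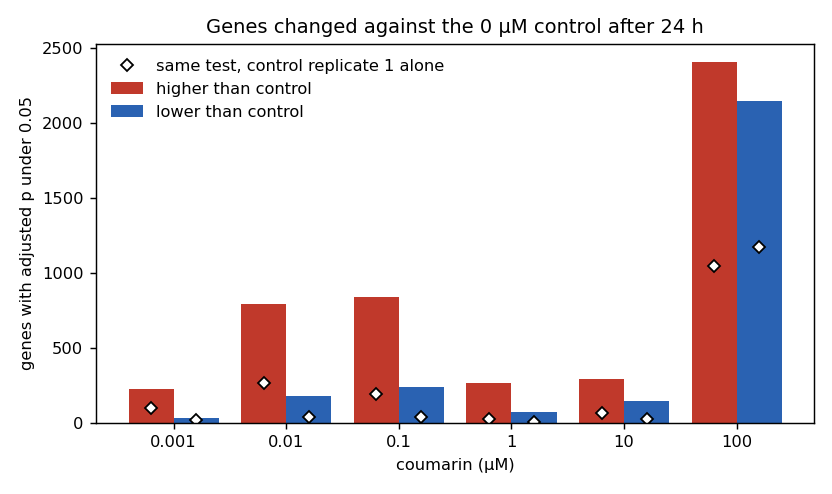
Number of genes higher (red bars) and lower (blue bars) than control at each coumarin dose at an edgeR adjusted p under 0.05, with 3 libraries per group. White diamonds give the numbers against control replicate 1 alone. Bars reach 2409 up and 2149 down at 100 µM, and 838 up and 239 down at 0.1 µM.

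Apart from the ATF4 list, the preset AHR and NF-kB lists fell at 100 µM and held with an estimated correlation. Of 8 measured AHR targets, 6 fell and 1 rose (7 and 1 adjusted over the list alone), with a median log2 change of -0.57 (camera adjusted p = 0.000128; 0.0211 with an estimated correlation). ALDH3A1 led, AHRR, the AHR repressor, fell by 0.73 and TIPARP, an AHR-induced ribosyltransferase gene, fell by 0.41. The member that rose was SLC7A5, an amino acid transporter gene, by 0.43. Of 14 NF-kB and inflammatory genes, 6 fell (7 adjusted over the list alone), with a median of -0.26 (camera adjusted p = 0.00158; 0.0408 with an estimated correlation). IER3, an early response gene, fell by 1.02 (edgeR adjusted p = 1.3e-20), TNFAIP2 fell by 0.66, the apoptosis inhibitor gene BIRC3 fell by 0.58 and TNFAIP3, an NF-kB inhibitor gene, fell by 0.31.

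**Figure D5:**
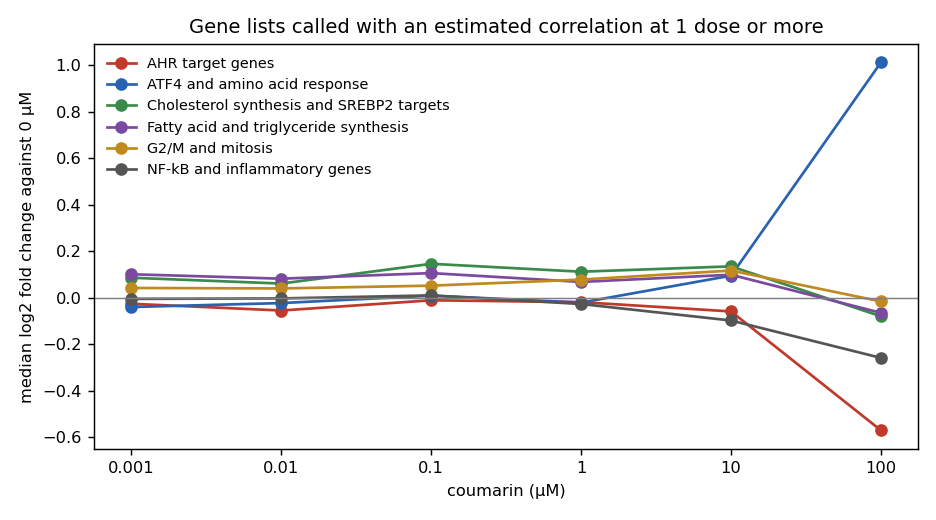
Median log2 change against control (vertical axis) by coumarin dose for the 6 preset lists called with an estimated correlation at 1 or more doses. The ATF4 list is at 0.10 at 10 µM and 1.01 at 100 µM and the AHR list at -0.57 at 100 µM, while the cholesterol list is at 0.14 at 10 µM and -0.08 at 100 µM.

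Genes of the protein synthesis machinery were higher at 100 µM, in lists whose calls did not hold with an estimated correlation. Of 39 cytosolic ribosomal protein genes, 35 rose (36 adjusted over the list alone; 31 with upper-quartile scaling), with a median log2 change of 0.19 (camera adjusted p = 6.08e-12; adjusted p = 0.312 with an estimated correlation). RPS18 rose by 0.38 and RPLP2 by 0.35. Of 20 ribosome biogenesis genes, 15 rose (18 adjusted over the list alone), led by NOLC1 at 0.45 and DKC1 at 0.35 (camera adjusted p = 3.27e-09; adjusted p = 0.0679 with an estimated correlation). Purine and pyrimidine synthesis had 11 of 21 genes up (13 adjusted over the list alone), with CTP synthase CTPS1 at 0.43 (adjusted p = 0.209 with an estimated correlation). The histone list had 5 of 12 genes up and 1 down both ways of adjusting, HIST1H2AC at 0.57 and HIST1H4H at -0.61 (adjusted p = 0.209 with an estimated correlation). Histone genes share sequence, and their values are uncertain for that reason. Immediate early genes had 11 of 19 up and 3 down (12 and 3 adjusted over the list alone; adjusted p = 0.284 with an estimated correlation). Heat shock genes had 9 of 15 up (10 and 1 down adjusted over the list alone; adjusted p = 0.297 with an estimated correlation). Nuclear genes of oxidative phosphorylation had 12 of 29 up and 1 down (13 and 1 adjusted over the list alone; adjusted p = 0.51 with an estimated correlation), and genes of DNA replication had 9 of 25 up and 1 down (10 and 2; adjusted p = 0.343 with an estimated correlation). The heat shock, oxidative phosphorylation and DNA replication lists also lost their calls against control replicate 1 alone (camera adjusted p = 0.202, 0.684 and 0.299) and with the share of reads outside genes as a covariate (0.0943, 0.468 and 0.255). The mean log2 change of the oxidative phosphorylation list was 0.089 against control and 0.01 against control replicate 1 alone. Against control replicate 1 alone the heat shock and DNA replication lists had means of 0.081 and 0.048. With the covariate these means were 0.097 and 0.056.

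The fibroblast marker, metal response and cholesterol synthesis lists were lower at the same dose, again without holding with an estimated correlation. Of 8 fibroblast markers, 4 fell by either adjustment, PDGFRB, a growth factor receptor gene, by 1.86-fold and the protease gene FAP by 2.55-fold (camera adjusted p = 0.00808; adjusted p = 0.0846 with an estimated correlation). Of 6 metallothionein and metal response genes, 4 fell by either adjustment, with MT2A, a zinc-binding protein gene, at a log2 change of -0.57 (adjusted p = 0.187 with an estimated correlation), a call also lost against control replicate 1 alone and with the covariate. The mean log2 change of this list was -0.36 against control replicate 1 alone and -0.325 with the covariate. Against the 12 libraries at 0.001 to 1 µM it was -0.296. Metallothionein genes share sequence, so single values are uncertain. Of 25 genes of cholesterol synthesis, 10 fell and 1 rose by either adjustment, with a median of -0.08 (camera adjusted p = 0.0119; adjusted p = 0.284 with an estimated correlation). FDFT1, squalene synthase, fell by 0.22 and INSIG1, a sterol-regulated gene, fell by 0.24.

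Several preset lists of xenobiotic and stress response were not called at 100 µM. Of 23 NRF2 targets, 7 rose and 9 fell (9 and 9 adjusted over the list alone), with AKR1C1, an aldo-keto reductase gene whose reads are shared with its paralogs, at -0.86. Of 21 p53 targets, 6 rose and 2 fell (7 and 2 adjusted over the list alone), among them the cell cycle inhibitor gene CDKN1A by 0.59 and the stress cytokine gene GDF15 by 0.73, while the median was -0.01 and the mean 0.10. Of 19 chaperones of the unfolded protein response, 6 rose and 4 fell by either adjustment, with a median of 0.03 that turned to -0.003 with upper-quartile scaling. Apoptosis regulators had 4 of 21 up and 3 down by either adjustment, with PMAIP1, a BH3-only gene, up by 0.82 and BMF, another, at -1.46. Interferon-induced genes had 1 of 18 up and 5 down by either adjustment, with IFIT1 at -0.75. Of 11 vitamin K cycle and coagulation genes, 5 fell by either adjustment, with the anticoagulant gene PROS1 at -0.19. CYP2A6, the coumarin 7-hydroxylase, had 0 to 5 counts per library and CYP3A4, a major hepatic drug oxidase, 0 to 1, so neither was tested. CYP1A1, an AHR-induced oxidase, was 2.32-fold lower at 100 µM (edgeR adjusted p = 0.00233) on 22 to 35 counts per control library and 10 to 15 at 100 µM. Its call was kept without any 1 library. It was lost in 2 of 13 other alternatives, 1 of them control replicate 1 alone. VKORC1, the vitamin K reductase that coumarin-derived drugs inhibit, fell by 0.17 (edgeR adjusted p = 0.0469), and NQO1, a quinone reductase, fell by 0.17 (edgeR adjusted p = 0.00107). The VKORC1 call ended without control replicate 1, 2 or 3 and without 100 µM replicate 1 or 2 (edgeR adjusted p of 0.0197 to 0.884 over the alternatives), and its log2 change was 0.01 against the 12 libraries at 0.001 to 1 µM.

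At 10 µM the same comparison with control showed lower retinoic acid hydroxylase and higher serine and asparagine synthesis transcripts, at smaller sizes. CYP26B1 was 1.92-fold lower (9.87 ± 1.31 against 19.2 ± 0.584 CPM, SD, n = 3; edgeR adjusted p = 1.68e-09), and it kept its call in every alternative and without any 1 library. In the ATF4 list 4 of 24 genes rose (5 adjusted over the list alone; 2 with upper-quartile scaling), with a median log2 change of 0.10 (camera adjusted p = 0.000236; 0.0476 with an estimated correlation). PSAT1 rose by 0.30 (edgeR adjusted p = 7.33e-06), NUPR1 by 0.20 and PHGDH by 0.16. ASNS rose 1.59-fold (edgeR adjusted p = 0.025), a call that ended whichever 1 of the 6 libraries compared was left out (edgeR adjusted p of 0.0103 to 0.219 over the alternatives). CHAC1 was at 0.24 (edgeR adjusted p = 0.469). Genes of mitosis and of cholesterol synthesis were also higher. Of 26 mitotic genes 5 rose (11 adjusted over the list alone; 4 with upper-quartile scaling), led by the proliferation marker MKI67 at 0.33 and AURKA, a mitotic kinase gene, at 0.20 (camera adjusted p = 6.9e-10; 0.0111 with an estimated correlation). Of 25 cholesterol synthesis genes 8 rose (15 adjusted over the list alone; 3 with upper-quartile scaling), with INSIG1 at 0.34 (camera adjusted p = 6.54e-10; 0.0209 with an estimated correlation). Against the 12 libraries at 0.001 to 1 µM both lists passed with smaller mean log2 changes, 0.033 in place of 0.125 for the cholesterol list (camera adjusted p = 0.0137) and 0.058 in place of 0.116 for the mitotic list (camera adjusted p = 8.4e-05). IER3 fell by 0.25 in an NF-kB list with 1 of 14 genes down by either adjustment (adjusted p = 0.0846 with an estimated correlation). The list call was also lost against control replicate 1 alone and with the covariate, where its mean log2 changes were -0.227 and -0.161. The remaining genes named by rule rose 1.5-fold (the cyclin gene CCNE1), 1.42-fold (IGFN1) and 1.31-fold (MN1), or were 1.95-fold (C2orf92), 1.92-fold (DCST1) and 1.90-fold (SSTR2, a somatostatin receptor gene) lower. Apart from IGFN1 these lost their calls against control replicate 1 alone, and against the 12 libraries at 0.001 to 1 µM all but DCST1 did. The calls of CCNE1, MN1, C2orf92, DCST1 and SSTR2 also ended without control replicate 3 and without 10 µM replicate 3.

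In total 437 genes changed at 10 µM (edgeR adjusted p under 0.05), 291 up and 146 down, 16 of them by at least 2-fold. With upper-quartile scaling 37.5% of the called genes were higher, against 66.6% with the main scaling. The count was 91 against control replicate 1 alone, 120 with the share of reads outside genes as a covariate, 213 in a fit of the 6 libraries alone, and 1189 with the GC and length trend removed. It was 226 without control replicate 2, 92 without control replicate 3, 268 without 10 µM replicate 2 and 263 without 10 µM replicate 3. Against the 12 libraries at 0.001 to 1 µM, a reference chosen after seeing the data, 438 genes changed (121 up, 317 down), and 100 of them also changed the same way against control.

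At 1 µM changes were small, with sterol and mitotic genes higher and the vasodilator peptide gene ADM lower. ADM was 2.13-fold lower (14.9 ± 3.42 against 31.5 ± 2.30 CPM, SD, n = 3; edgeR adjusted p = 0.00136), a call kept without any 1 library but lost against control replicate 1 alone, with the share of reads outside genes as a covariate and in a fit of the 6 libraries alone (adjusted p of 1.43e-09 to 0.116 over the alternatives). Of 25 cholesterol synthesis genes 5 rose (14 adjusted over the list alone, 2 with upper-quartile scaling; camera adjusted p = 3.96e-09; 0.0211 with an estimated correlation). Of 26 mitotic genes 3 rose (8 adjusted over the list alone; 1 with upper-quartile scaling), with MKI67 at 0.30 (camera adjusted p = 2.92e-06; 0.0363 with an estimated correlation). Of 24 proteasome genes 4 rose (12 adjusted over the list alone), PSMA4 by 0.22 and PSMD1 by 0.19 (adjusted p = 0.136 with an estimated correlation). Of 19 chaperones of the unfolded protein response 3 rose (5 adjusted over the list alone), HYOU1 and CALR by 0.21 each and CANX by 0.18 (adjusted p = 0.234 with an estimated correlation). The proteasome and chaperone lists also lost their calls against control replicate 1 alone (camera adjusted p = 0.0797 and 0.467) and with the covariate (0.154 and 0.675). The sarcomere gene TNNT2 rose 1.45-fold, the ribosomal protein gene RPL38 1.38-fold, IGFN1 1.34-fold and the translocon gene SEC61G 1.32-fold, while SSTR2, C2orf92 and NYAP1 were 1.90-fold, 1.86-fold and 1.71-fold lower. Of the 8 genes named by rule, 1 (IGFN1) passed against control replicate 1 alone, and all but ADM lost their calls without control replicate 2 and without 1 µM replicate 1. In total 335 genes changed, 263 up and 72 down (55.4% up with upper-quartile scaling, among 213 genes, against 78.5%). The count was 31 against control replicate 1 alone, 11 with the covariate and 851 with the GC and length trend removed. It was 663, 128 and 38 without control replicates 1, 2 and 3, and 89 and 77 without 1 µM replicates 1 and 2.

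At 0.1 µM the list of sterol genes was higher. ATP5ME, an ATP synthase subunit gene, rose 1.78-fold (37.4 ± 3.5 against 21.0 ± 1.59 CPM, SD, n = 3; edgeR adjusted p = 0.013), the mitochondrial gene MT-ATP8 rose 1.77-fold and the ribosomal protein gene RPS29 rose 1.72-fold. The presynaptic gene CPLX1 rose 1.77-fold from 1.10 ± 0.222 CPM. MYH7B, a myosin gene, was 1.77-fold lower, the proton pump gene ATP6V0C 1.72-fold, the protease gene PRSS27 1.62-fold and DUSP6, an ERK phosphatase gene, 1.54-fold. None of these 8 genes kept its call against control replicate 1 alone or with the share of reads outside genes as a covariate, and each lost it in 3 to 6 of the 6 fits that left out 1 library. Of 25 cholesterol synthesis genes 9 rose (15 adjusted over the list alone; 6 with upper-quartile scaling), with INSIG1 at 0.21 (camera adjusted p = 6.86e-07; 0.0408 with an estimated correlation). In total 1077 genes changed, 838 up and 239 down (55.3% up with upper-quartile scaling against 77.8%). The count was 233 against control replicate 1 alone and 11 with the covariate. It was 624 and 451 without control replicates 2 and 3, and 417 and 472 without 0.1 µM replicates 1 and 2.

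At 0.01 µM glycolysis and immediate early genes and mitochondrially encoded transcripts were higher, in lists that did not hold with an estimated correlation. EGR1, an early growth response transcription factor gene, rose 2.72-fold (5.59 ± 1.23 against 2.06 ± 0.333 CPM, SD, n = 3; edgeR adjusted p = 2e-04), and FOS, a subunit of the transcription factor AP-1, rose 1.72-fold (45.6 ± 5.42 against 26.5 ± 2.05 CPM). Of 19 immediate early genes 5 rose (10 up and 1 down adjusted over the list alone), with NR4A1 at 0.33 (camera adjusted p = 0.000902; adjusted p = 0.234 with an estimated correlation). Glycolysis genes rose in 6 of 21 cases (13 adjusted over the list alone), with the glucose transporter gene SLC2A1 at 0.33 and hexokinase HK1 at 0.25 (camera adjusted p = 6.8e-08; adjusted p = 0.209 with an estimated correlation). Of 17 YAP and TGF-beta response genes 5 rose (7 adjusted over the list alone), with the receptor kinase gene AXL at 0.28 and CTGF at 0.26 (adjusted p = 0.0787 with an estimated correlation). Mitochondrially encoded transcripts rose in 6 of 13 cases (11 adjusted over the list alone; 3 with upper-quartile scaling), MT-ATP8 by 1.97-fold (camera adjusted p = 6.8e-08 for the list; adjusted p = 0.299 with an estimated correlation). This call was lost with the covariate (mean log2 change 0.104 against 0.33, camera adjusted p = 0.216). It was kept without any 1 library, and the mean was 0.214 against control replicate 1 alone. The largest mitochondrial share was that of 0.01 µM replicate 3 (8.747% against 7.474% and 7.044%), which also had the smallest share of reads outside genes. CYP11A1, a steroid side-chain cleavage enzyme gene, rose 1.77-fold, and ADM was 1.61-fold, CDKL3 1.73-fold, CKLF 1.82-fold and ANKHD1-EIF4EBP3 1.55-fold lower, the last pair uncertain because they overlap other genes. None of the 8 genes named by rule passed against control replicate 1 alone, and CYP11A1, CKLF, CDKL3 and ANKHD1-EIF4EBP3 also lost their calls without control replicate 2. In total 978 genes changed, 796 up and 182 down (65.1% up with upper-quartile scaling against 81.4%). The count was 302 against control replicate 1 alone and 38 with the covariate. It was 439 without control replicate 3, and 487 and 569 without 0.01 µM replicates 2 and 3.

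At 0.001 µM ADM and DDIT4 were lower and fatty acid synthesis genes higher. ADM was 2.6-fold lower (12.2 ± 0.751 against 31.5 ± 2.30 CPM, SD, n = 3; edgeR adjusted p = 0.000241), and DDIT4, a stress-induced inhibitor of mTOR signalling, was 1.41-fold lower (196 ± 8.61 against 276 ± 5.45 CPM; edgeR adjusted p = 5.03e-07). Both kept their calls in every alternative and without any 1 of the 6 libraries compared. ADM did not follow dose, with means of 19.5, 27.7, 14.9, 30.1 and 28.6 CPM at 0.01, 0.1, 1, 10 and 100 µM. A p-value from the spread within groups does not measure variation between groups that is unrelated to dose. Of 17 genes of fatty acid and triglyceride synthesis 2 rose (9 adjusted over the list alone), the desaturase gene SCD and ACACA, acetyl-CoA carboxylase, each by 0.23, and FASN, fatty acid synthase, was at 0.29 (edgeR adjusted p = 0.0573). The list was called (camera adjusted p = 6.79e-06; 0.039 with an estimated correlation) in every alternative. TBC1D3E rose 2.15-fold, but it shares reads with near-identical copies. The scaffold gene AHNAK2 rose 1.32-fold, and the phosphatase gene PTPN23 and the transcription factor gene FOXP4 each rose 1.29-fold. TMEM256 was 1.41-fold and the complex I subunit gene NDUFB8 1.29-fold lower. PTPN23 kept its call in every alternative, and the other 5 of these genes lost theirs without 0.001 µM replicate 3. In total 256 genes changed, 224 up and 32 down (76.3% up with upper-quartile scaling against 87.5%). The count was 119 against control replicate 1 alone, 95 with the covariate, 95 in a fit of the 6 libraries alone, 414 with the GC and length trend removed and 421 with DESeq2. It was 59 without control replicate 3 and 47 without 0.001 µM replicate 3.

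Over the 6 doses, 70 of 210 list tests were called (60 up, 10 down), and 10 of these held with an estimated correlation (8 up, 2 down). All 10 kept their calls in every other alternative. Against control replicate 1 alone 37 list tests were called (24 up, 13 down), and with the share of reads outside genes as a covariate 55 (26 up, 29 down), so the excess of rises was not kept with the covariate. That covariate was higher in control than in treated groups, so it can also absorb rises due to treatment. It followed the TMM factors of the same counts, so calls lost with it do not show an effect of reads outside genes. Of the 41 lists, 6 had fewer than 5 measured genes and were not tested, among them PXR and CAR targets, whose most abundant measured gene was the exporter ABCC2 at 161 CPM.

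The mean of all treated groups against control asked what separated treated from untreated cells at any dose, and FAM129A was higher. It rose 1.33-fold (edgeR adjusted p = 6.32e-10), with 48.6 ± 0.673 CPM at 0.001 µM and 115 ± 3.06 CPM at 100 µM against 41.8 ± 0.926 in control (SD, n = 3). Also higher were RPS29 by 1.61-fold, ATP5ME by 1.59-fold, MT-ATP8 by 1.54-fold and RPL38 by 1.38-fold, and CPLX1 by 1.5-fold. GABARAP, an autophagy gene, was 1.57-fold lower, C2orf92 1.65-fold, SSTR2 1.62-fold, RANBP3L 1.58-fold, CKLF 1.57-fold and ANKRD61 1.48-fold. With 1 control library fewer changes can pass, and a lost call does not show that a change is absent. FAM129A was the 1 of these 12 genes that passed against control replicate 1 alone (edgeR adjusted p of 0.000301, the highest over its alternatives, the lowest being 2.26e-22). All but FAM129A and RPL38 lost their calls without at least 1 of the control replicates. In total 1407 genes differed, 958 higher and 449 lower in treated cells (42.2% higher with upper-quartile scaling against 68.1%). The count was 177 against control replicate 1 alone, 124 with the covariate and 2305 with the GC and length trend removed, and it was 671 and 428 without control replicates 2 and 3.

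Among treated cells alone, a dose trend asked which genes moved steadily from 0.001 to 100 µM, and it leaves the controls out. CHAC1 rose by 0.69 on the log2 scale per 10-fold dose, ASNS by 0.55, INHBE by 0.47, ADM2 by 0.46 and DDR2 by 0.43. CYP26B1 fell by 0.35 per 10-fold dose (edgeR adjusted p = 0.000313), LBH fell by 0.34, CYP26A1 fell by 0.31, BDKRB2 fell by 0.29 and AC254633.1, a long noncoding RNA gene (ENSG00000272482, chromosome 1, 12618900 to 12619244) fell by 0.37. Without the 100 µM group CYP26B1 (edgeR adjusted p = 0.0281) and AC254633.1 kept their trends, and the other 8 did not pass, with CHAC1 at an adjusted p of 0.107. In total 3555 of 16522 genes had a trend, 1655 upward and 1900 downward, and 2402 of these changed the same way at 100 µM against control, 20 the opposite way. Without the 100 µM group 432 genes had a trend (177 up, 255 down).

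A test for any difference over the 7 doses called 5008 genes (edgeR adjusted p under 0.05), of which 3576 also changed at 100 µM against control and 1432 did not. The overlap of calls at 10 µM with those at 100 µM was large in both directions. Of the 291 genes up at 10 µM, 213 were also up at 100 µM, where independent lists would share 42, and of 146 down, 108 were also down, against 18.8. The log2 changes at both doses correlated across genes at r = 0.539, against 0.506 in simulations of unchanged groups that share the controls. At 0.001, 0.01, 0.1 and 1 µM r was lower than in the simulations (0.373 against 0.494, 0.391 against 0.506, 0.418 against 0.496 and 0.417 against 0.502). The simulated 100 µM group was unchanged, and larger real changes there can lower r, so r is not directly comparable. The covariance at 10 µM was 0.0518 against 0.0221 in the simulations, a difference of 0.0297, and that difference was 0.0116 for 0.001 µM, 0.0158 for 0.01 µM, 0.0209 for 0.1 µM and 0.0176 for 1 µM. At 0.001, 0.01, 0.1 and 1 µM the genes also up at 100 µM were 92, 285, 368 and 158, against 32.3, 115, 121 and 37.9 for independent lists, and those also down were 15, 66, 97 and 42, against 4.12, 23.4, 30.8 and 9.27. The simulations shared a mean of 0 to 0.05 genes, but called only 0.1 to 0.25 genes per dose. Opposite directions were held by 22, 123, 97, 20 and 12 genes from 0.001 to 10 µM. Part of the overlap beyond independent lists may come from the shared controls, which are too few to split.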

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

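The tests of the hepatocyte transcripts and of endoplasmic reticulum stress below were chosen only after the results were seen, as were control replicate 1 alone, the GC and length correction and the low-dose reference. Genes of cholesterol synthesis went opposite ways at the highest pair of doses: the list's mean log2 change was 0.125 at 10 µM and -0.089 at 100 µM, and the difference of -0.214 passed its own test (limma camera adjusted p = 8.02e-11 over 35 lists; 0.00312 with an estimated correlation). The fall at 100 µM alone did not hold (adjusted p = 0.284 with an estimated correlation), and against the 12 libraries at 0.001 to 1 µM the means were 0.033 and -0.181.

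At the 4 lowest doses 256 to 1077 genes were called, most of them higher than control. A bias with GC content or transcript length is argued against as the whole cause, since 83.4% of the calls were also made in the same direction with that trend removed. Of the genes called at 0.001 or 0.01 µM, 30.7% (309 of 1007) moved further the same way between the mean of 0.1 and 1 µM and 100 µM. For most of these genes this goes against a response that goes on growing with dose. It does not exclude one hidden by differences between libraries, which also ran over the treated groups. The mean share of reads outside genes was 6.70% in control, 2.51% and 2.72% at 0.1 and 1 µM, and 3.49% at 100 µM. The second principal component was 8.16 to 19.9 in control libraries, -13.6 to 6.52 at 0.1 and 1 µM, and -1.06 to 2.70 at 100 µM. An offset of control replicates 2 and 3, which held the largest shares of reads outside genes, cannot be told apart from a treatment effect. For 1513 genes called between those controls and the treated libraries, the median difference was 0.198. Against control replicate 1 it was 0.083 (41.9%), and 80.2% of genes kept their direction. Holding out replicate 2 or 3 instead kept 76.4% or 106%. Most of the 1007 genes moved back instead, since 248 of 809 rises and 61 of 198 falls went further. Of all genes, 50.7% were higher at 100 µM in that contrast. A plateau up to 100 µM, or an offset of 2 control libraries alone, would not by itself give this return. Neither is excluded, since genes that vary together can shift the share and 3 controls are too few to settle an offset. A non-monotone response to coumarin stays open.

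Most preset hepatocyte transcripts were near the floor in all 21 libraries of cells labelled HepG2. The preset factors NR2F1 and NR2F2 had 83.1 and 40.5 CPM. CPS1 and PRSS56, chosen after their values were seen, had 4690 and 6310 CPM. That the authors' counting or filtering removed the preset hepatocyte genes is argued against, since 17 of the 22 preset secreted-protein genes had at least 1 count in some library. A candidate explanation is that the cells were not hepatocyte-like cells, since 4 of 15 preset hepatocyte transcription factors reached 1 CPM, but this test was chosen from the same libraries. Culture conditions shared by all 21 libraries cannot be told apart from it, since no library was grown otherwise. No design group gives a biological explanation to test.

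The ATF4 and amino acid response list rose at 100 µM. An offset of the control libraries is argued against, since the mean rise of the list against the 12 libraries at 0.001 to 1 µM was 103% of that against control. Endoplasmic reticulum stress cannot be told apart from other triggers of this response here, but the unfolded protein response chaperones did not rise as a set. Their median log2 change was 0.029, with 6 members up and 4 down. Against the 12 libraries at 0.001 to 1 µM their mean log2 change was -0.006. A response to coumarin at this dose may account for the rise, a hypothesis found and tested on the same data.

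Regrouping the libraries gave the following. For the comparisons of 1 dose with control the 10 possible splits of 6 libraries are too few for a share under 0.05, and in each only the real split, 1 of 10, gave as many genes. The real and the highest other counts were 256 and 27 at 0.001 µM, 978 and 13 at 0.01 µM, 1077 and 0 at 0.1 µM, 335 and 0 at 1 µM, 437 and 52 at 10 µM, and 4558 and 1 at 100 µM. At an unadjusted p under 0.05 by edgeR the real splits had 2003, 3168, 3338, 2444, 2631 and 6183 genes from 0.001 to 100 µM. The highest such counts among all other splits were 1995, 1972, 1620, 2004, 2334 and 1471. The separation was therefore small by this measure at 0.001 and 10 µM. In under 5% of splits, the real one alone, was the result as large for the 7-dose test (5008 genes against at most 1853 in 60 splits), for all treated against control (1407 against 5 in 60), for the trend (3555 against 1 in 80) and for the list calls (70 against 66 in 60). Other splits came close for the list calls and reached 1853 genes for the 7-dose test, and the cause was not tested, since regrouped libraries can keep libraries of 1 dose together. Regrouping also mixes the 100 µM libraries with others, which can widen the fitted spread and lower the counts of other splits. Nor can it tell an offset of control libraries from a treatment effect.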

How the results depend on the processing

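The alternatives chosen only after seeing the data were control replicate 1 alone, the share of reads outside the counted genes as a covariate, removal of the GC and length trend, and the 12 libraries at 0.001 to 1 µM as reference. Of 245 counts under alternatives 185 stayed within 1.5 times the main count, of 2685 list results 2421 kept their call and direction, and of 1905 named gene results 1574 did. All 24 genes named by rule at 100 µM kept call and direction in every alternative run. Unless said otherwise the cause of a change was not tested.

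Counts at 0.001, 0.01, 0.1, 1, 10 and 100 µM were 119, 302, 233, 31, 91 and 2222 against control replicate 1 alone, where fewer libraries enter, and 95, 38, 11, 11, 120 and 2800 with the covariate. For all treated against control they were 177 and 124, and 37 list tests were called with control replicate 1 alone. The covariate differs between control and treated groups and can absorb a treatment effect. It also follows the TMM factors of the same counts and is not an independent measure. With the GC and length trend removed, counts were 414 at 0.001 µM, 851 at 1 µM, 1189 at 10 µM and 2305 for all treated. At an adjusted p under 0.01 they were 90, 467, 437, 100, 138 and 2966, and at a fold of at least 2 they were 5, 18, 24, 7, 16 and 311, as stricter limits allow fewer. A fit of the 6 libraries alone gave 95 at 0.001 µM and 213 at 10 µM. At 0.001 µM no filter gave 394, DESeq2 421, and limma on FPKM plus 1 and plus 0.1 gave 144 and 155. Upper-quartile scaling gave 213 at 1 µM. The trend without the 100 µM group gave 432 genes. With an estimated correlation 10 list calls remained.

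Leaving out 1 library at a time gave 47 to 326 genes at 0.001 µM, 439 to 1073 at 0.01 µM, 417 to 1278 at 0.1 µM, 38 to 663 at 1 µM, 92 to 649 at 10 µM, 3516 to 4318 at 100 µM, 428 to 1561 for all treated, 3710 to 5631 over the 7 doses, 2386 to 3839 for the trend and 57 to 89 list calls. Without control replicate 3 the counts at 1 and 10 µM were 38 and 92.

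List results that reversed did so by the direction of the camera test, and the values are mean log2 changes, some of which keep their sign. With the covariate these were the unfolded protein response at 0.01 (-0.006) and 0.1 µM (-0.009), DNA replication (-0.005), mitochondrial transcripts (0.011) and proteasome (-0.018) at 0.1 µM, heat shock (-0.03), glycolysis (-0.031), oxidative phosphorylation (-0.022), mitochondrial transcripts (-0.031) and ribosomal proteins (-0.046) at 1 µM, ribosomal proteins at 10 µM (-0.01), and mitochondrial transcripts (-0.077), proteasome (-0.024) and apoptosis regulators (-0.014) at 100 µM. With control replicate 1 alone these were the unfolded protein response at 0.001 µM (-0.012), heat shock (-0.03), oxidative phosphorylation (-0.013) and ribosomal proteins (0.01) at 1 µM, DNA replication (0.004) and ribosomal proteins (0) at 10 µM, and mitochondrial transcripts (-0.022), proteasome (-0.028), hepatocyte transcription factors (-0.144) and apoptosis regulators (0.008) at 100 µM. With the low-dose reference these were fatty acid synthesis at 10 µM (0.007), and the unfolded protein response (-0.006), mitochondrial transcripts (-0.128), proteasome (-0.014) and hepatocyte transcription factors (-0.007) at 100 µM, and VKORC1 at 100 µM (0.013). With the GC and length trend removed mitosis at 100 µM reversed (0.009), and without 0 µM replicate 1 glycolysis (-0.019) and autophagy (0) at 100 µM did, the lowest values without 1 library being -0.051 and -0.042 (without 0 µM replicate 2).

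The labels give every group replicates 1, 2 and 3, but same-numbered control and dose libraries deviated together by r of -0.0994 to 0.0515 in 18 pairs across genes, and 9 of 21 libraries correlated best with their own number, so the numbers do not pair the libraries. With the replicate block the counts were 238, 931, 978, 323, 376 and 4446 from 0.001 to 100 µM, 1325 for all treated, 3295 for the trend, 4810 over the 7 doses and 69 list calls, and no count moved by over 1.5 times. Depth limits what can be said of genes under about 1 CPM, such as CYP2A6 and CYP3A4, which were not tested.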

Other observations

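The test of the retinoic acid target list was planned before its values were seen, but it was chosen only after other results were seen. The idea came from CYP26A1, CYP26B1 and TGM2, which were named by rule, and from RARRES1 and HRASLS2, which were not. Results beyond the named genes were therefore seen first, and the choice of the list may not be blind to them. Of 11 measured genes of that list 3 fell at 10 µM and 7 at 100 µM. STRA6, which encodes the cell surface receptor that takes up retinol, had 92.9 ± 4.16 CPM in control, 64.4 ± 4.09 at 10 µM and 33.8 ± 1.04 at 100 µM (SD, n = 3; edgeR adjusted p = 1.39e-08 and 3.72e-23). DHRS3, a retinaldehyde reductase gene, went from 104 ± 4.52 to 82.5 ± 5.06 and 46.5 ± 2.21 CPM. The epithelial transcription factor gene ELF3 fell by 0.92 on the log2 scale at 100 µM and HOXA3, a homeobox gene, fell by 0.80, while RARA, a retinoic acid receptor gene, fell by 0.20 (edgeR adjusted p = 0.0157) and CRABP2, a retinoic acid binding protein gene, was at -0.19 (edgeR adjusted p = 0.374).

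A hypothesis is that signalling through retinoic acid receptors may be lower at 10 and 100 µM. It was tested on 20 known retinoic acid targets that leave out CYP26A1, CYP26B1, RARRES1, HRASLS2 and TGM2, which prompted it. Of these 20 genes 11 were measured, 7 fell and 0 rose at 100 µM by edgeR, and their median log2 change was -0.418 (limma camera p = 1.5e-07; 0.000223 with an estimated correlation). At 10 µM 3 fell and the median was -0.277 (limma camera p = 4.41e-08; 0.000152 with an estimated correlation). Against the 12 libraries at 0.001 to 1 µM the medians were -0.478 and -0.315. The values are those the hypothesis needs, but the list was tested on the libraries that raised it, and receptor activity and retinoic acid were not measured.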
